A study of Caenorhabditis elegans with 2 samples.

How the data were processed

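The samples were 2 biological replicates of ChIP-seq with an antibody against GFP in whole young adult hermaphrodites of strain YL482, which express a GFP and FLAG fusion of SNPC-1.1, per the labels. Both formed 1 group. The labels name a possible control, which was not analysed here. Per the labels, chromatin was fragmented by sonication, and the assemblies were ce11 and ce10. The aligner, the peak caller, their versions and the reproducibility threshold are not given in the sources used here.

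The deposited values were 8 peak lists: 4 kinds of list, each on 2 genome builds. Per the text files deposited with them, the authors called at most 30000 regions on each replicate and on the pooled replicates against a control alignment, and kept a set of peaks that passed an irreproducible discovery rate (IDR) threshold across replicates. The signal value of each region is a score given by the authors, on a scale that is not stated, and was used only to rank and describe regions within a list. The column for p-values held no values and the column for q-values was negative in some lists, so neither was used. On ce11 the 1500 reproducible peaks were the 1500 regions of highest signal in the pooled list, so an analysis of the top pooled regions gives the same result by construction. The summit was the region start plus the deposited offset; for 1332 of the 1500 reproducible peaks the offset was the middle of the region. Some regions in the lists overlap, and merging them would remove 32 peaks. The lists give no read totals, so depth per sample is unknown, and intervals given for shares of peaks or genes cover counting error only.

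Gene positions came from the Ensembl release 115 annotation of WBcel235, whose coordinates are those of ce11, and the sequence from the matching RefSeq assembly. All peak ends lay within the chromosome lengths, and a mitochondrial peak ended at 13794, the length of that chromosome. Coordinates are 1-based. Genes were put into 12 classes by their annotated type; snRNA genes were divided into SL1, SL2 and the rest, called U snRNA here, since the annotation does not give the type of each. tRNA genes of the mitochondrial genome were kept apart from nuclear ones. In some cases several identical copies are listed under 1 symbol and were counted as separate genes.

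A peak was near a gene when its summit was within 500 bp of the annotated start. For each class, the number of peaks near a member was compared with 1000 circular shifts, each moving all summits of a chromosome by 1 random distance and wrapping at the chromosome end (seed 20). The two-sided permutation p was 2 times the smaller tail, so 0.002 is the smallest that the shifts can give, and values were adjusted over 12 classes by the Benjamini-Hochberg method. The same shifts were used for the number of members of 12 gene lists with a peak, adjusted over the lists, and for the number of peaks inside the published piRNA domains of chromosome IV, 4.5 to 7.0 Mb and 13.5 to 17.2 Mb. Shares of genes or peaks have exact (Clopper-Pearson) 95% binomial intervals. The gene lists covered SNAPc and piRNA transcription factors, the piRNA pathway, RNA polymerase III noncoding genes, histones, ribosomal proteins, germline, sperm, intestine, hypodermis, muscle, neuron and heat shock genes. The listed names snpc-1.4, snpc-1.5, snpc-3.3, prg-2, tofu-3, rde-3, srpr-1.3, srpr-1.4, srpr-1.5, opt-2, hsp-16.11 and daf-21 were not found in the annotation used and were left out.

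Words of 8 bases, with both strands merged, were counted in windows of 50 bp either side of the summit and in windows of the same length 1000 bp up- and downstream, leaving out flanks that overlap a reproducible peak. Each word was tested with Fisher's exact test and adjusted over all 32896 words. The set of 10 words was the leading words at peaks near SL2 or snoRNA starts and not near U snRNA starts. Replicates were compared by the share of reproducible peaks that overlap, by at least 1 bp, a region among the 1500 of highest signal in each replicate, and by the Spearman rank correlation across peaks, where each peak took the overlapping region of highest signal. Of the 1500 peaks, 9 had no region in one of the replicates and were left out of the correlation. A bootstrap of 1000 draws over peaks gave the interval of this correlation used to judge alternatives.

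The genes named in the text were fixed by rule before the data were examined: all genes with a start within 500 bp of the 25 highest peaks (of piRNA genes only the nearest), up to 3 members with the highest peaks in each class or list, all members of the SNAPc and piRNA transcription factor list, and the 5 highest peaks with no start nearby. For the germline and piRNA pathway lists, every member with a peak was named, a choice made after the values were seen. The positions of summits relative to starts, their shares by part of the genome, the set of 10 words and its test by group of peaks, the Fisher tests between tissue lists and between groups of peaks overlapped by the highest regions of both replicates, and the counts inside and outside the domains by kind of start were not among the tests fixed before the data were examined. The alternatives were windows of 200 and 1000 bp, the 750 peaks of highest signal, merged peaks, the 1500 highest regions of either replicate alone, local shifts of 5 to 50 kb, nearest start only, omission of peaks at SL1 and 5S genes, bins of 10 kb with at least 5 piRNA genes in place of the domains, other overlap criteria, other windows and flanks for words, and the ce10 lists. Local shifts moved each summit by its own random distance, where the main shifts moved all summits of a chromosome together. Alternatives without the mitochondrial peaks, with copies of 1 symbol counted once and without the genes shared by the piRNA pathway and germline lists were added after the data were seen.

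The class, list, domain and word tests were tested on simulated data, and the other tests were not. With 60 peaks planted at tRNA starts among 1500 random summits, the class test called tRNA genes in 20 of 20 simulations, and with nothing planted it called a class in 0 of 20. For the list test, 10 planted germline genes were called in 20 of 20 simulations, and no list was called without planting. The random summits had no preference for gene starts, so the simulations do not cover list calls that stem from such a preference. Without planting, the domain test gave a call in 1 of 20 simulations. A word planted in 60 of 1500 windows ranked 1 of 32896, and 4 words were called. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.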

Results

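The data describe where the protein SNPC-1.1 was found on the genome of young adult Caenorhabditis elegans hermaphrodites. SNPC-1.1 is a worm homologue of a subunit of the small nuclear RNA activating protein complex (SNAPc), which in animals binds promoters of small nuclear RNA genes. Worms of strain YL482 carried a transgene for the protein fused at its C terminus to GFP and FLAG, and chromatin was immunoprecipitated with an antibody against GFP (ChIP-seq). There was 1 group of 2 biological replicates, with no second condition, so no test between groups of samples was possible. The lists gave peak regions but no read totals, so the sequencing depth is unknown and no interval that needs it is given. On build ce11 the authors' lists held 1500 reproducible peaks, 30000 regions from the pooled replicates, 29523 regions from replicate 1 and 26195 from replicate 2. The reproducible peaks had a median width of 320 bp (range 80 to 571). Their signal values, the authors' own score per peak on a scale not stated, ran from 58.8 to 10087 with a median of 84.8.

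Among nuclear peaks, the strongest were mostly at noncoding genes for small RNAs. Of the 25 peaks with the highest signal, 20 lay within 500 bp of the start of a tRNA, U snRNA, SL2 or snoRNA gene, 3 lay on the mitochondrial genome, 1 lay at a gene of the remaining noncoding class and 1 had no gene start nearby. At all 20 the small RNA gene was an SL2 or snoRNA gene. Of all 1500 peaks, 420 (28.0%) lay by one of the 4 small RNA classes (tRNA, U snRNA, SL2 and snoRNA), with a median signal of 103. By class, the median signal was 938 at SL2, 313 at U snRNA, 150 at snoRNA and 83.8 at tRNA peaks, against 84.8 for all peaks. The tRNA peaks were thus not stronger than the whole set. A further 571 (38.1%) lay by a protein-coding start and by none of these 4 classes, though some of them also lay by other noncoding starts, with a median signal of 77.5. No annotated start was within 500 bp of 397 nuclear peaks (26.5%), and 27 peaks were mitochondrial, with a median signal of 678. Among the 100 highest peaks, 67 belonged to the small RNA classes, 14 were mitochondrial and 4 belonged to the group with a protein-coding start and no small RNA start. Here and below, small RNA start means these 4 classes only. The peak at mrpr-1, the RNA gene of RNase MRP, is therefore counted in that last group.

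The first comparison asked which classes of gene start lay near the summits more often than chance. Genes for SL2, the spliced leader added to downstream genes of operons, stood out most: 18 peaks lay near an SL2 start, against 0.292 expected, 61.6 times as many. U snRNA genes, which encode spliceosomal RNAs, had 70 peaks (4.67%) against 1.39 expected, 50.2 times as many. Nuclear tRNA genes had 237 peaks (15.8%) against 7.51 expected, or 31.6 times, and snoRNA genes, whose products guide RNA modification, had 99 (6.60%) against 4.98, or 19.9 times. Expected numbers are means over 1000 circular shifts of the summits along each chromosome, with standard deviations of 0.560, 1.24, 2.84 and 2.19 for these 4 classes. Each of the 4 had a permutation p of 0.002, the smallest that the shifts can give, and an adjusted p of 0.0040 over 12 classes.

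Smaller excesses were found for the class of other noncoding RNAs, with 321 peaks (21.4%) against 85.6 expected, for protein-coding genes, with 664 (44.3%) against 296, and for miRNA genes, with 11 (0.733%) against 3.34. The adjusted permutation p was 0.0040 for the first of these, 0.0040 for protein-coding genes and 0.00685 for miRNA genes. A peak could count for several classes. Counting each peak only for its nearest start left 123 peaks in the class of other noncoding RNAs. Pseudogenes (21 peaks, 29.5 expected, adjusted permutation p = 0.225), lncRNA genes (3 peaks, 2.82 expected, adjusted permutation p = 1) and rRNA genes (5 peaks, 4.20 expected, adjusted permutation p = 0.988) did not differ from chance. Pseudogenes passed the threshold, below chance, with a window of 1000 bp (2.13% of peaks against 3.81% expected, adjusted permutation p = 0.0103) and with nearest starts only (1.00% against 1.76%, adjusted permutation p = 0.0373). The nearest-start count loses peaks to the classes in excess, so that second shortfall is partly built in. Of the rRNA peaks, 1 was nuclear, so the rRNA count says little about nuclear rRNA genes.

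Seen from the genes, 17 of 18 SL2 genes had a summit within 500 bp of the start (94.4%, exact 95% binomial interval 72.7 to 99.9%). The share was 59 of 99 (59.6%, 49.3 to 69.3%) for U snRNA genes, 264 of 612 (43.1%, 39.2 to 47.2%) for nuclear tRNA genes and 96 of 346 (27.7%, 23.1 to 32.8%) for snoRNA genes. By contrast, none of the 12 annotated genes for SL1, the other spliced leader, had a peak (0%, upper bound 26.5%). The SL1 genes lie in repeated copies, and the median share of 36-base words within 150 bp of their starts that occur once in the genome was 0. Of the 40 U snRNA genes without a peak, 14 had less than 0.5 of such words occurring once and 15 had 0.9 or more, against 8 and 9 of the 59 with a peak. Among protein-coding genes 850 of 19985 had a summit near the start (4.25%, 3.98 to 4.54%), and among piRNA genes 171 of 15363 (1.11%, 0.953 to 1.29%). Members that lie next to each other can share a peak, so these intervals treat neighbouring genes as independent when they are not.

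**Figure D1:**
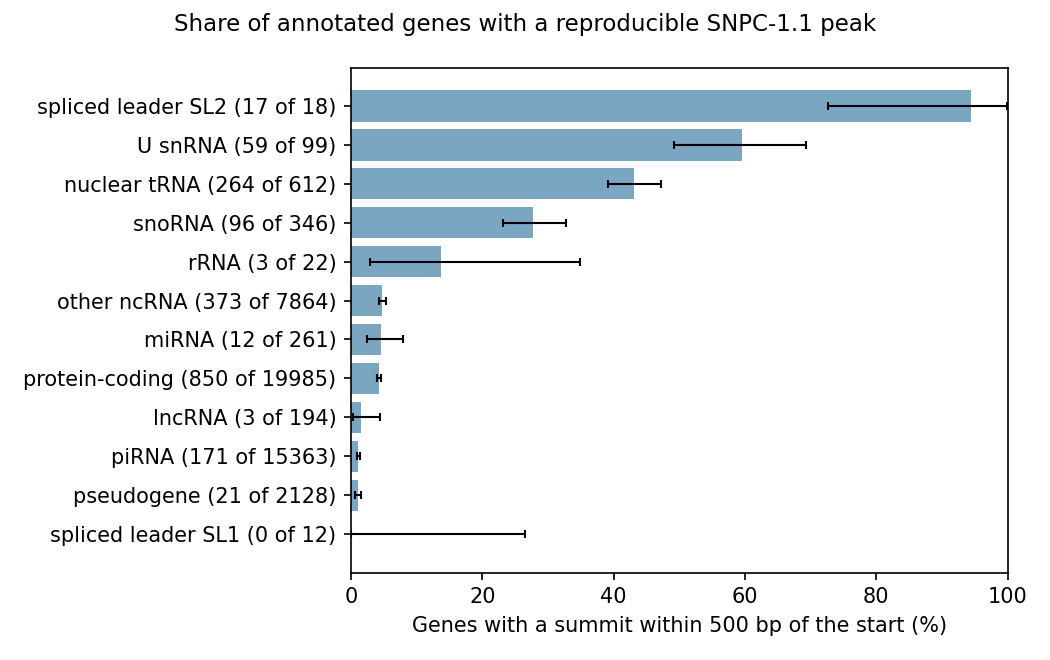
Percentage of annotated genes of each class with a reproducible SNPC-1.1 summit within 500 bp of the start, with the number of genes in brackets; bars give the percentage and lines the exact 95% binomial interval. SL2 genes were at 94.4% and U snRNA genes at 59.6%, while SL1 genes were at 0%.

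The highest nuclear peak, with a signal of 2984, had its summit at 15025963 on chromosome II, 70 bp upstream of the snoRNA gene Y53F4B.47 (15025814 to 15025893) and 151 bp upstream of cmtr-1, a cap methyltransferase gene on the other strand. The next was at sls-2.16, an SL2 gene on chromosome III (7141391 to 7141499), with a summit 27 bp upstream of the gene, a signal of 2915 and the noncoding gene B0280.22 nearby. The snoRNA genes W04D2.7 (chromosome V, 12491280 to 12491346, signal 2721) and ZK994.7 (chromosome V, 8500579 to 8500645, signal 2624) followed, the first overlapped by the noncoding gene W04D2.14. The peak at the SL2 gene sls-2.8 (chromosome III, 12250465 to 12250575, signal 2421) also lay within 500 bp of the protein-coding genes tim-1 and Y75B8A.23 and the noncoding gene Y75B8A.49. Other genes that the annotation types as snoRNA among the 25 highest peaks were C08D8.3, C16D9.11, Y55F3BR.9, F01D5.12, Y74C9A.6, K07C10.2, C07A9.14, Y37E3.20, C16D9.10, T06D8.11, smy-3 and T26A8.6, with signals from 2340 at C08D8.3 to 1614 at T26A8.6. The annotated type was not checked gene by gene. The remaining SL2 genes in this set were sls-2.4, sls-2.1 and sls-2.18, with signals of 1998, 1892 and 1564. The noncoding genes C08D8.6, Y55F3BR.17, F01D5.14, K07C10.6, R12E2.18, Y37E3.29, C16D9.13, T06D8.17, T06D8.13 and B0280.21 and the protein-coding gene D1086.3 had starts beside the same summits. The noncoding gene ZK265.11 (chromosome I, 8245547 to 8245622) stood alone at a signal of 1938.

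Below these came F42C5.12, sup-6 and H27M09.6, the U snRNA genes with the highest peaks, with signals of 1378, 1370 and 1347 and summits 35, 39 and 34 bp upstream of the starts. The highest tRNA peaks had signals of 1113 at WBGene00022945 on chromosome II, 1045 at WBGene00014446 on chromosome I and 1031 at WBGene00014617 on chromosome V. Of the 237 tRNA peaks, 7 were among the 100 highest, against 13 of the 18 SL2 peaks, 18 of the 70 U snRNA peaks and 31 of the 99 snoRNA peaks. The miRNA genes with the highest peaks were cel-mir-8196b (signal 1064), cel-mir-8196a (773) and cel-mir-794 (168). The single nuclear rRNA gene with a peak was rrn-4.15 on chromosome V (17428879 to 17428996, signal 437), 1 of 15 annotated 5S genes there. How much of the sequence around the 5S genes occurs once in the genome was not examined. Among lncRNA genes, linc-60, linc-44 and linc-1 had peaks with signals of 77.3, 72.0 and 61.4. The pseudogenes with the highest peaks, WBGene00045045, WBGene00045037 and WBGene00018127, all lay on chromosome IV, with signals of 591, 386 and 281. The summit at WBGene00045045 also lay within 500 bp of a tRNA, U snRNA, SL2 or snoRNA start.

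Genes for other short noncoding RNAs made by RNA polymerase III also had peaks. They were found at 3 of the 5 listed genes that were annotated: rpr-1, the RNA of RNase P (chromosome I, 13463955 to 13464207, signal 1298, summit 44 bp upstream), mrpr-1, the RNA of RNase MRP (chromosome II, 7200233 to 7200418, signal 711, 37 bp upstream), and yrn-1, the Y RNA (chromosome IV, 7499508 to 7499612, signal 383, 22 bp upstream). The shifts gave 0.0940 on average (adjusted permutation p = 0.0060 over 12 lists).

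Summits took different places relative to the start at different classes of gene. The median summit was 43 bp upstream of the start at U snRNA genes (n = 59), 40 bp upstream at SL2 genes (n = 17) and 42.5 bp upstream at snoRNA genes (n = 96). All 17 SL2 summits were upstream, as were 86.4% of U snRNA and 88.5% of snoRNA summits. At tRNA genes (n = 264) the median lay 10.5 bp inside the gene, with 45.1% of summits upstream. The tRNA and U snRNA medians differed by 53.5 bp (two-sided permutation p = 2e-05, the smallest that 100000 resamples can give). At protein-coding genes (n = 850) summits were spread more widely, with a median of 188.5 bp upstream and quartiles of 306 and 92 bp upstream. Over the whole set, 53.1% of summits were intergenic, 22.6% intronic, 6.27% in UTRs and 3.07% in coding exons, where these parts make up 33.4%, 32.7%, 4.65% and 24.5% of the genome. A further 9.73% lay inside small RNA genes, here with miRNA, rRNA, SL1 and mitochondrial tRNA genes included, which make up 0.145% of the genome. The remaining 5.20% lay in other noncoding genes, which make up 4.56%.

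**Figure D2:**
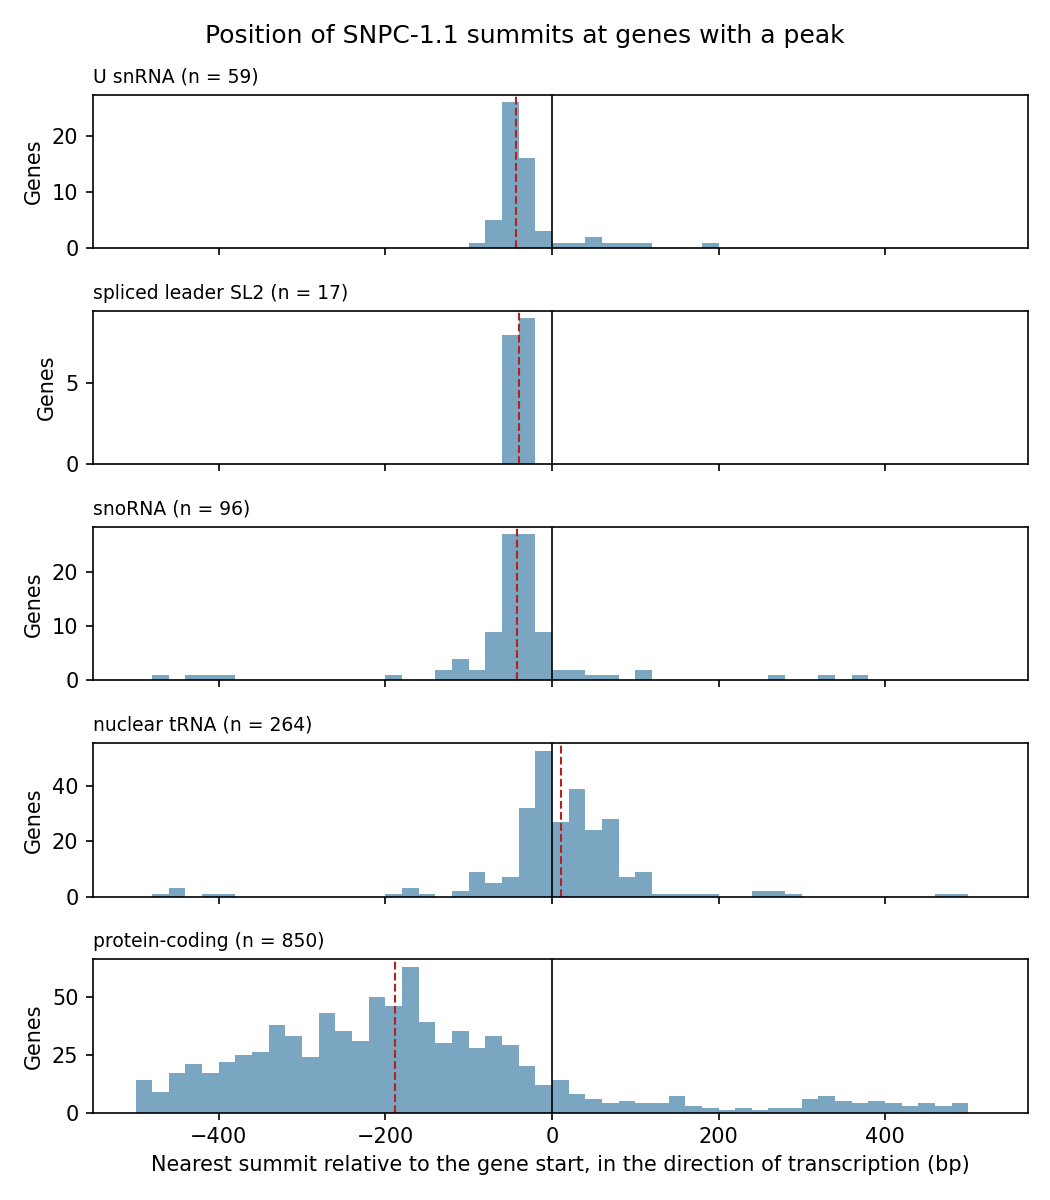
Position of the nearest SNPC-1.1 summit relative to the gene start in the direction of transcription (bp, bins of 20 bp), as numbers of genes with a peak in 5 classes; the solid line marks the start and the dashed line the median. U snRNA, SL2 and snoRNA summits gather near 40 bp upstream, tRNA summits lie around the start, with a median 10.5 bp inside the gene, and protein-coding summits are spread mostly upstream.

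Of the gene lists fixed beforehand, ribosomal protein genes had the most members with a peak: 44 of 81 (54.3%), against 1.24 expected (adjusted permutation p = 0.0060). The highest were rpl-15 (chromosome IV, signal 591, summit 360 bp upstream), rpl-20 (chromosome IV, 454, 283 bp upstream) and rpl-3 (chromosome III, 350, 273 bp upstream). The median signal of the 42 peaks behind these genes was 91.2, 1 of them was among the 100 highest, and 4 also lay within 500 bp of a small RNA start. Germline genes followed with 8 of 25 members (32.0%) against 0.382 expected (adjusted permutation p = 0.0060). They were mex-5, puf-5, pos-1 and oma-2, which encode RNA-binding proteins of oocytes and early embryos, rme-2, the yolk receptor, glh-2 and pgl-3, which encode germ granule proteins, and egg-1, an oocyte surface protein. Signals were 158 at mex-5, 134 at puf-5 and 117 at rme-2, and between 65.7 and 90.4 at the other members. With a window of 200 bp, 9 ribosomal protein and 4 germline genes had a peak, and with the 750 highest peaks 26 and 4 (adjusted permutation p = 0.0080 for each). Expected numbers for the lists come from shifted summits. Since 4.25% of all protein-coding genes had a peak, part of any excess at a protein-coding list is common to that class.

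The piRNA pathway list had 4 of 24 members with a peak against 0.355 expected (adjusted permutation p = 0.0060): znfx-1, a germ granule helicase gene (signal 143, summit 389 bp upstream), the Argonaute genes wago-4 (405th by signal, 205 bp upstream) and hrde-1 (signal 80.7, 213 bp upstream), and tofu-6 (signal 68.8, 57 bp upstream). This call was lost with a window of 200 bp, where 1 member was left (adjusted permutation p = 0.686), and among the 750 peaks of highest signal, where 2 were left (adjusted permutation p = 0.0719). The share of 16.7% was not tested against the 4.25% of all protein-coding genes with a peak, so an excess beyond that class was not shown. The list shares glh-1 and pgl-1 with the germline list, and neither had a peak. Heat shock genes had 2 of 16 members, hsp-6 (signal 81.8) and ubq-2 (64.9), against 0.207 expected (adjusted permutation p = 0.120). With a window of 1000 bp the number was 5 (adjusted permutation p = 0.0060), and against local shifts of 5 to 50 kb the main number passed (adjusted permutation p = 0.0240). Local shifts move each summit separately, so that p treats peaks that lie together as independent. The gene ubq-2 encodes a ubiquitin fused to a ribosomal protein.

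Peaks were few or absent at the other lists. The tagged gene itself, snpc-1.1 (chromosome II, 7779297 to 7781301), had no peak within 500 bp of its start. Of the 13 annotated members of the SNAPc and piRNA transcription factor list, snpc-3.4 had one (chromosome III, 4020037 to 4021883, signal 114, summit 4 bp inside the gene in the UTR), against 0.214 expected (adjusted permutation p = 0.787). No peak lay at brf-1, prde-1, snpc-1.2, snpc-1.3, snpc-3.1, snpc-3.2, snpc-4, tbp-1, tofu-4, tofu-5 or unc-130. Histone genes had 2 of 72, the neighbours his-67 and his-68, which share 1 summit (1.09 expected, adjusted permutation p = 0.971). The histone number was 6 in replicate 1 alone (adjusted permutation p = 0.0815), 4 in replicate 2 alone (adjusted permutation p = 0.272) and 5 with a window of 1000 bp (adjusted permutation p = 0.412). Of muscle genes, act-2 alone of 19 had a peak (signal 66.8, 0.254 expected, adjusted permutation p = 0.788). The sperm (38 genes), intestine (16), hypodermis (15) and neuron (18) lists had none, where the shifts gave 0.574, 0.203, 0.196 and 0.270 (adjusted permutation p = 1 for each). With so few expected, these lists could not have shown a depletion. Set directly against the germline list, the intestine, hypodermis, muscle and neuron lists together had 1 of 68 members with a peak (1.47%, exact 95% interval 0.0372 to 7.92%), a lower share than 8 of 25 (two-sided Fisher exact p = 7.86e-05).

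A further comparison asked whether SNPC-1.1 lay at piRNA genes, nearly all of which (14714 of 15363) sit on chromosome IV, most of them in a pair of domains on that chromosome. Near piRNA starts there were 83 peaks (5.53%), against 80.0 ± 18.8 (SD over 1000 shifts) expected (adjusted permutation p = 1). The direction of this difference depended on the reference. Against local shifts of 5 to 50 kb the expected share was 6.79% (adjusted permutation p = 0.00685). Those shifts moved each summit by its own distance, so peaks that lie together were treated as independent, unlike in the main shifts. Counting only the nearest start, there were 38 peaks (2.53%) against 4.88% expected (adjusted permutation p = 0.0210). A peak with a start of another class closer drops out of that count. Other classes were in excess at the real summits, so this shortfall is partly built in. The share near piRNA starts was also below the expected share, short of the threshold, with a window of 200 bp (2.33% against 3.61%) and in replicate 1 alone (5.80% against 5.98%) and replicate 2 alone (5.13% against 5.17%). The piRNA genes beside the highest peaks were 21ur-14704 on chromosome II (signal 953, summit 271 bp upstream), 21ur-13723 on chromosome IV (824, 497 bp upstream) and 21ur-7591 on chromosome IV (777, 231 bp downstream of the start). Each of these summits also lay within 500 bp of a tRNA, U snRNA, SL2 or snoRNA start, so they cannot be assigned to the piRNA genes. Summits near piRNA starts were spread on both sides, with 48.5% upstream.

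The piRNA domains held 146 of the 294 peaks on chromosome IV, or 23.5 per Mb against 13.1 per Mb on the rest of the chromosome. The shifts gave 105 ± 27.8 (SD), so the excess was within what shifting the same peaks along the chromosome produces (permutation p = 0.166). Of the 146 peaks inside, 46 lay by a small RNA gene of the 4 classes, 44 by a protein-coding start and no small RNA start, 35 by other starts only and 21 by none, and 62 were within 500 bp of a piRNA start. Outside, 6 of 148 peaks were near a piRNA start. The domains hold 2816 and 11388 of the 14714 piRNA genes on the chromosome. Gene density alone would give a contrast of this kind, and it was not tested against that.

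**Figure D3:**
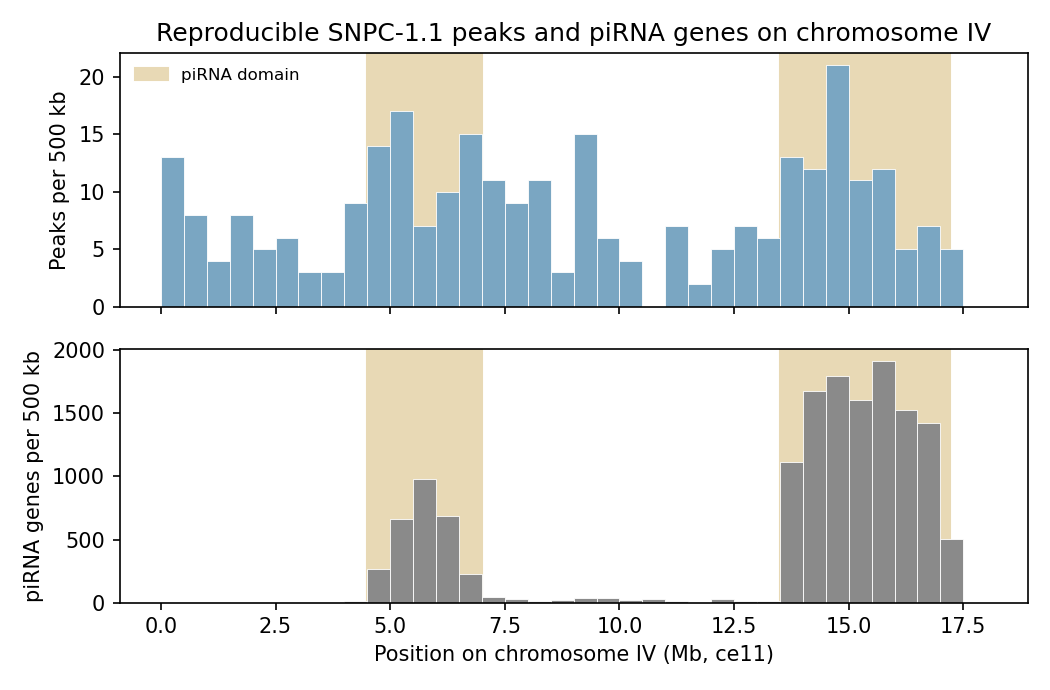
Reproducible SNPC-1.1 peaks (upper panel) and annotated piRNA genes (lower panel) per 500 kb along chromosome IV (Mb, ce11), with the piRNA domains shaded. Bins that begin inside the domains held 5 to 21 peaks and the other bins 0 to 15, while piRNA genes reached 1915 per bin inside the domains.

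Some strong peaks had no annotated start nearby. The highest nuclear one lay between genes on chromosome IV (991078 to 991403, summit 991256, signal 1585). The next lay in introns on chromosome II (13521907 to 13522171, signal 1251) and chromosome III (6210265 to 6210545, signal 1029). On the mitochondrial genome the highest peak of the whole set (summit 4756, signal 10087) fell in a coding exon of WBGene00000829, within 500 bp of the tRNA genes WBGene00014464, WBGene00014463, WBGene00014462 and WBGene00014461. Another (summit 13171, signal 2263) was upstream of the tRNA gene WBGene00014473. The mitochondrial peaks at 12301 to 12582 (signal 6085) and 8707 to 9026 (signal 943) had no start within 500 bp, and the rRNA genes WBGene00014472 and WBGene00014454 had peaks of 887 and 801. The 27 mitochondrial peaks covered 6596 of 13794 bp (47.8%).

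Short sequence words were compared between summits and flanks to describe the DNA under the peaks. The word GCGGAACC was in 155 of 1499 summit windows (10.3%) and in 2 of 2880 flanking windows (0.0694%), and CGGCCGAC was in 147 (9.81%) and 6 (0.208%), with Fisher exact adjusted p = 5.32e-67 and 4.72e-58. Of 32896 words of 8 bases, 1256 were more frequent at summits and 214 less frequent (Fisher exact test, Benjamini-Hochberg adjusted). The word CTGTTTCA, from the known upstream motif of piRNA genes, was at 3 summits (0.200%) and in 39 flanks (1.35%; Fisher exact adjusted p = 0.00311), a difference that no longer passed without the peaks near piRNA starts (0.212% against 0.699%, Fisher exact adjusted p = 0.342).

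A set of 10 words was taken from SL2 and snoRNA peaks alone, led by CGGAACCC (21 of 115 summits, 0 of 217 flanks), AACCCGCG, CGGGTTCC, GCGGAACC, GAACCCGC and GGCCGACA. At U snRNA peaks, which were not used to choose them, 25 of 70 summits held at least 1 of these words (35.7%, exact 95% interval 24.6 to 48.1%) against 1.49% of flanks (Fisher exact p = 1.70e-11). Some of these 70 peaks overlap each other, with 58 left after merging, so the interval and p treat as independent what is not. The share was 8.09% at tRNA peaks without another small RNA gene (19 peaks with a word), against 1.77% of flanks (Fisher exact p = 0.000110), and 6.83% of the 571 peaks with a protein-coding start and no small RNA start, against 0.810% (Fisher exact p = 1.14e-11). None of 42 ribosomal protein summits (upper bound 8.41%) and none of 26 mitochondrial summits (upper bound 13.2%) held one. Among the 85 peaks with other starts only, 34 did (40%, 29.5 to 51.2%), against 1.19% of flanks (Fisher exact p = 1.37e-16). Among the 397 nuclear peaks with no gene start, 146 did (36.8%, 32.0 to 41.7%), against 0.516% of flanks (Fisher exact p = 8.89e-72).

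Nearly all reproducible peaks had a region in both replicates, among them 416 of 420 small RNA peaks and 569 of 571 peaks with a protein-coding start and no small RNA start. Of the 1500 reproducible peaks, 1150 (76.7%, exact 95% interval 74.4 to 78.8%) overlapped 1 of the 1500 highest regions of replicate 1, and 1269 (84.6%, 82.7 to 86.4%) those of replicate 2. The peaks were themselves chosen from these replicates, so high overlap was largely built in. In both replicates at once, 962 (64.1%) were overlapped by such regions. Set against each other, 971 (64.7%) of the 1500 highest regions of replicate 1 were overlapped by those of replicate 2. Peaks overlapped by these highest regions in both replicates made up 74.3% of the small RNA peaks and 55.9% of the peaks with a protein-coding start and no small RNA start (two-sided Fisher exact p = 2.36e-09). The first group also had the higher median signal, 103 against 77.5, and these regions were chosen by signal. Across 1491 peaks with a region in both replicates, the Spearman rank correlation of the signal values was 0.596 and Pearson's r of their log10 values 0.869. These correlations are across peaks, which are not independent replicates, so no p-value is given. In each replicate alone, the 1500 highest regions touched 17 of 18 SL2 genes and 59 of 99 U snRNA genes, of which 17 and 58 were shared. For tRNA genes the numbers were 226 in replicate 1 and 272 in replicate 2, with 168 shared.

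**Figure D4:**
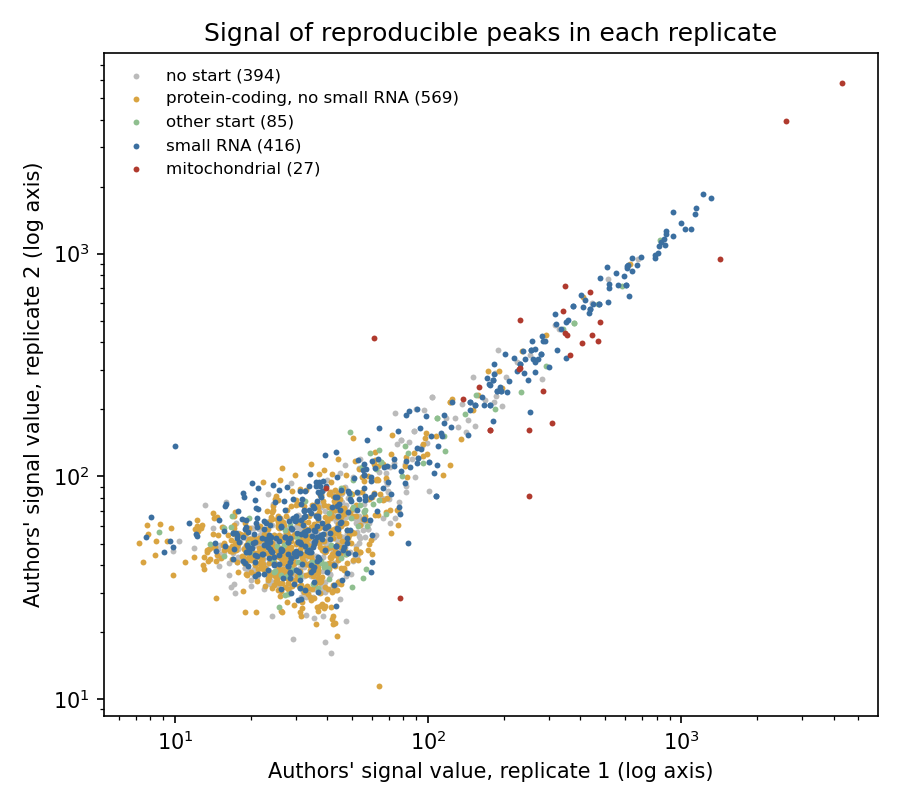
Authors' signal value of the overlapping region in replicate 1 (x axis) and replicate 2 (y axis) for 1491 reproducible peaks, both on log axes, with each point a peak coloured by what its summit lies near. Rank correlation was 0.782 for the 416 small RNA peaks, 0.580 for the 394 peaks with no start and 0.343 for the 569 peaks with a protein-coding start and no small RNA start. Peaks were selected by pooled signal, with a lowest value of 58.8. The protein-coding group, with a median of 77.5, lies near that cut, which can lower its correlation.

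The authors' lists on the older build ce10 were close to those on ce11 in number, width and signal of the reproducible peaks. They held 1516 reproducible peaks with a median width of 316 bp and a median signal of 84.3, against 1500, 320 bp and 84.8 on ce11. Chromosome IV had 300 and 294 of them, the X chromosome 196 on either build and the mitochondrial genome 29 and 27. Replicate 1 had 30000 regions on ce10 and 29523 on ce11. Coordinates were not converted between builds, so the identity of single peaks was not compared, and gene classes, lists, domains and words were examined on ce11 only.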

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

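The test of regions below the reproducible set was not among those fixed before the data were examined. Pooled regions ranked 1501 to 3000 by signal, which no comparison of the report uses, lay near starts of 6 gene classes more often than shifted summits did. Among these regions 128 lay near a nuclear tRNA start (7.29 expected, adjusted permutation p = 0.0060), against 237 in the reproducible set. For snoRNA genes the number was 19 (5.21 expected, adjusted permutation p = 0.0060) and for U snRNA genes 7 (1.5 expected, adjusted permutation p = 0.00959). Protein-coding starts had 695 regions (283 expected, adjusted permutation p = 0.0060), other noncoding RNA genes 184 (84.9 expected, adjusted permutation p = 0.0060) and miRNA genes 9 (3.3 expected, adjusted permutation p = 0.0343). These regions touched 146 of the 348 tRNA genes that had no reproducible peak, and 6 of the 40 U snRNA genes. Near piRNA starts there were 51 of these regions, fewer than the 77.9 expected (adjusted permutation p = 0.0120).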

How the results depend on the processing

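No paired analysis was possible because there was 1 group of samples. Of 400 values under an alternative, 347 were judged unchanged. They kept their direction and side of the threshold, stayed within their interval or, for plain counts with neither, were judged close to the main count. All those added after the data were seen were judged unchanged. The excess at protein-coding, tRNA, U snRNA, SL2, snoRNA, miRNA and other noncoding genes held under every alternative run, and the piRNA domain count did not pass the threshold under any. The pooled list gave identical values by construction. Depth is unknown, so its effect could not be assessed. For the values below the cause was not tested, except where fewer peaks or another window change a count by construction.

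The share of peaks near piRNA starts was 5.53% against 5.33% expected. It fell below the expected share with a window of 200 bp (2.33%), with nearest starts only (2.53%), against local shifts (5.53%) and in either replicate alone (5.13 to 5.80%). Classes with few peaks also changed side of their expected share. For lncRNA genes this was so at 200 bp (0.0667%), in the 750 highest peaks (0%) and with nearest starts only (0.133%). For rRNA genes it was so with merged peaks (0.272%), nearest starts only (0.200%), without array peaks (0.267%) and in either replicate alone (0.267 to 0.267%). Pseudogenes fell below chance past the threshold at 1000 bp (2.13%) and with nearest starts only (1.00%). With nearest starts only, the excess of other classes lowers such shares by construction.

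The percentage of genes with a peak moved with the window. At 200 bp it was 1.96% for protein-coding, 0.338% for piRNA, 3.76% for other noncoding genes and 0.329% for pseudogenes. At 1000 bp it was 5.78%, 2.41%, 5.80% and 1.60% for these, 47.2% for tRNA and 32.9% for snoRNA genes. With the 750 highest peaks it was 1.81% for protein-coding, 0.670% for piRNA, 20.6% for tRNA, 2.30% for miRNA, 0% for lncRNA, 2.86% for other noncoding genes and 0.517% for pseudogenes. In either replicate alone it was 36.9 to 44.4% for tRNA, 3.87 to 4.24% for protein-coding and 0.944 to 1.19% for piRNA genes.

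Of the lists, the piRNA pathway fell short of the threshold at 200 bp (1 gene) and in the 750 highest peaks (2), and heat shock genes passed it at 1000 bp (5) and against local shifts (2). Heat shock and muscle genes had 0 at 200 bp and in the 750 highest peaks, muscle had 0 to 1 in either replicate alone, and sperm genes had 3 at 1000 bp.

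Overlap with replicate 1 was 73.9% for summits within 100 bp, 74.1% for an overlap of 50% of both intervals and 82.3% for the 750 highest peaks. Against all regions it was 99.5% for replicate 1 and 99.9% for replicate 2. The Spearman rank correlation of the replicates was 0.728 in the 750 highest peaks. Words more frequent at summits numbered 1915 with windows of 100 bp either side, against 1256.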

Other observations

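The tests by gene-name family, by X linkage, of the tissue lists against ribosomal protein genes, of the numbers of U snRNA genes with few or many unique words and of mitochondrial coverage were chosen after the result was seen.

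Among protein-coding genes, peaks gathered in some gene-name families and were rare in others. Of 419 families of at least 5 genes that share a name prefix, 11 passed a Fisher exact test against the 10896 genes so named, of which 587 (5.39%) had a peak, and 8 of the 11 were above that share. Besides ribosomal proteins, with 24 of 47 rpl and 20 of 31 rps genes (Fisher exact adjusted p = 3.15e-16 for each), these were 4 of 5 atp genes (mitochondrial ATP synthase, 0.00335), 4 of 6 syp genes (synaptonemal complex, 0.00801), 5 of 11 rpb genes (RNA polymerase II subunits, 0.00940), and 4 of 8 each of the mcm (DNA replication), puf (RNA binding) and rsp (splicing) genes (0.0205 each), all by the same exact test. No peak lay at any of 269 nhr genes (nuclear receptors, Fisher exact adjusted p = 9.06e-05) or 193 str genes (chemoreceptors, Fisher exact adjusted p = 0.00335), and 2 of 220 srh genes had one (Fisher exact adjusted p = 0.0288).

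The X chromosome had few protein-coding starts with a peak: 24 of 2731 (0.879%, exact 95% interval 0.564 to 1.3%) against 814 of 17242 on autosomes (4.72%, 4.41 to 5.05%; Fisher exact adjusted p = 5.85e-27 over 4 classes). A loss of all peaks on X was tested as the explanation and was not borne out for tRNA genes, of which 47.1% on X had a peak against 39.9% on autosomes (Fisher exact adjusted p = 0.0849). In the remaining classes the share was lower on X, short of the threshold: 4 of 33 snoRNA genes (12.1%) against 29.4% (Fisher exact adjusted p = 0.0801) and 0 of 3 U snRNA genes against 61.5% (Fisher exact adjusted p = 0.0840), so a loss on X stays open for these. The log odds ratio of X against autosomes for protein-coding genes minus that for tRNA genes was -1.99 (standard error 0.263, over genes, which are not replicates).

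Peaks with no annotated start that held 1 or more of the 10 words from SL2 and snoRNA peaks, called element words here, numbered 146, of which 87 (59.6%) were intronic and 42 (28.8%) on X, against 77 of 251 (30.7%) and 21 (8.37%) of such peaks without the words; this difference was not tested. The highest by signal were on chromosome II (13521907 to 13522171), chromosome III (6210265 to 6210545) and chromosome I (8761173 to 8761332). Copies of a repeated sequence were weighed as an explanation before the value was seen. A median of 0.996 of the 36-base words around these summits occurred once in the genome, which argues against exact copies for most of the set, although 15 of the 146 had a value under 0.5. Diverged copies of a repeat stay open, since only exact matches of 36 bases were counted. Whether unannotated genes start there was not tested.

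For the genes without a peak, shared reads and a missing element were weighed. At the 12 SL1 genes the median share of 36-base words that occur once was 0, as reads shared between identical gene copies would need, and no pooled region of any rank lay at them. At the 40 U snRNA genes without a peak this share was 0.716, between the bounds set beforehand, against 0.658 at the 59 with a peak. Shares under 0.5 were more frequent without a peak (14 against 8 genes, Fisher exact p = 0.0148), which goes with shared reads for part of the genes, but so were shares of 0.9 or more (15 against 9 genes, Fisher exact p = 0.0164), so for the class as a whole shared reads cannot be told apart from other explanations. An element word lay in the 100 bp upstream of 49.2% of U snRNA genes with a peak and 10% of those without (Fisher exact p = 3.51e-05). A missing element is thus a candidate explanation. Of the 40 genes without a peak, 20 had a pooled region of lower rank, as did 6683 of 19135 protein-coding genes without a peak. For those 20, the lack of a peak may partly reflect the threshold.

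At ribosomal protein genes, peaks from neighbouring small RNA genes, the words' element and promoter use in any tissue were weighed. Of the 42 peaks, 9.5% lay within 500 bp of a small RNA start (exact 95% interval 2.66 to 22.6%), which argues against neighbours as the main source. The upstream element of SL2 and snoRNA genes was at 0% of their summits against 35.7% at U snRNA peaks (Fisher exact p = 2.19e-06). Lists for intestine, hypodermis, muscle and neuron had 1.47% of members with a peak against 54.3%. This contrast cannot decide on a signal common to highly used promoters of any tissue, which stays open. Promoter use was not measured, and in whole animals the genes of a tissue may be used in only some of the cells. Promoter use in the germline and indirect recovery of open chromatin stay open as untested, since the design has 1 group and no control library was analysed here.

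On the mitochondrial genome, 14 of the 100 highest peaks were found. The coverage was 47.8%, and the median distance to the nearest start was 229 bp, against 206 bp for shifted summits (permutation p = 0.470). Both met the bounds, set after the result was seen, for many mitochondrial genome copies as the source. They cannot show it. With 27 summits the distance test could miss a preference for starts. Regions were called against a control alignment, in which such copies would also count, and the control was not analysed here. The upstream element of SL2 and snoRNA genes was at 0% of the mitochondrial summits (upper bound 13.2%), which argues against binding through that element. No biological explanation other than this element was tested.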
